A study of Mus musculus with 10 samples.

How the data were processed

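RNA of T-antigen immortalized mouse embryonic fibroblasts was measured in 10 libraries, 5 kept at 2% CO2 and 5 at 10% CO2 for 24 h. Per the labels' protocols, cells were collected in RNA/DNA Shield, RNA was extracted with beads by a sequencing company, and mRNA was turned into cDNA by reverse transcription and second-strand synthesis, tagmented, indexed and amplified. Such reads carry no statement of strand or of molecular identifiers in the labels. Per the submitters' processing notes, STAR 2.7.11, SAMtools 1.22.1, featureCounts of Subread 2.1.1 and MultiQC 1.32 were used with genome build GRCm39. Their settings, order and gene annotation are not given in the sources used here.

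The deposited values are estimated counts per gene and library, which are not normalized. Between 71.0% and 79.2% of the nonzero values of a library are whole to within 1e-06, and the rest are fractions, which a division of shared reads among genes can give. How the fractions arose is not given in the sources used here. Fractional counts occurred in 822 of the 1588 genes called, and for members of families with near-identical copies or pseudogenes the values are uncertain. A second deposited table holds CPM (counts scaled to a library total of 1e6), which the authors' values show to be the counts divided by the library total: the greatest difference was 4.8e-05 CPM in batch 1 and 8.2e-11 CPM in batch 2. It was used only for that check. The table has 78317 genes and 92 spike-in entries, all at 0 counts, which were left out. No genome of build GRCm39 was used here, so no coordinates are given, and gene names are those of the files.

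Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by CO2 level (minimum count 10, minimum total 15), TMM scaling, robust quasi-likelihood fits and F tests with a model of batch plus CO2, and Benjamini-Hochberg adjusted p under 0.05, two-sided. Log2 fold changes are 2% minus 10% CO2, and CPM means are over the 5 libraries of a level. The CO2 by batch interaction was tested in a model with that term, and batch genes by the batch term of the first model. Gene lists, 39 in all, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, for the 34 lists with at least 5 tested members, adjusted over the lists. Each list also has the count of members called over all genes and adjusted over the list alone. Where a symbol has several identifiers, the one with the most counts was used.

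The design, the lists, the alternatives and the rule for naming genes were set before the data were examined. Named were the 12 highest and 12 lowest log2 fold changes among called genes with a mean of at least 5 CPM, the same direction in both batches and a symbol that is not a predicted or clone name, up to 4 members of each list with the smallest adjusted p, 24 genes of autophagy, lysosome and pH regulation whether called or not, and the 3 leading interaction genes, of which there were none. The rule gave 130 tested genes, of which 118 were called, and 77 of these stayed called in every fit that left out a library.

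Replicate numbers are shared between the CO2 levels. After removing the means of the CO2 levels, same-numbered libraries deviated together in all 5 pairs (correlations 0.80, 0.36, 0.52, 0.89 and 0.54), which the batch alone can give, since the labels tie the number to a batch. After removing batch means as well, the correlations were 0.47, 0.04, 0.11, 0.43 and -0.24. The replicate number as a block was therefore tried beside the batch term. None of the 8 library pairs within a CO2 level and batch agreed within sampling noise, so none of these was counted as a duplicate, and pairs across levels or batches were not compared.

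Depth ran from 178676 to 12354538 counts. On simulated counts with the means and totals of these libraries (12917 genes tested), edgeR recovered 40.3% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 90.9% of those changed 3-fold, and 8.00% of its calls were unchanged genes. In 5 draws that thinned every library to 178428 counts, between 3501 and 3541 genes were tested and between 156 and 167 were called. Alternatives were RLE and library total scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of 10 CPM in 5 libraries, each library left out, no batch term, each batch alone, a fold threshold of 1.2, thinning, fry and an estimated correlation. Added after seeing the data were fits without the 3 shallowest libraries, with GC and length trends removed (96.7% of tested genes had both values, from transcripts of another build used only as gene properties), camera with voom weights, and a second way of thinning.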

Results

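Messenger RNA was profiled in wildtype mouse embryonic fibroblasts immortalized with T antigen, a viral oncoprotein that inactivates p53 and the retinoblastoma protein and so lets primary cells divide without limit. The cells were grown in complete medium at 37 °C and 10% CO2, and were then held for 24 h either at 10% CO2 or at 2% CO2 (hypocapnia, a CO2 level below the one the culture was kept at). The title of the series places the comparison in the study of how CO2 affects autophagy, the delivery of cytoplasmic material to lysosomes for breakdown. There were 5 libraries at each CO2 level, of which replicates 1 to 3 belonged to batch 1 and replicates 4 and 5 to batch 2, and the labels do not say what the batches were.

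Depth was uneven. In batch 1 the 10% CO2 libraries held 5694026, 8985537 and 8101893 estimated counts for replicates 1, 2 and 3, against 2621598, 178676 and 506405 at 2% CO2. In batch 2 the order was turned, with 10607076 and 892318 counts for replicates 4 and 5 at 10% CO2 and 12354538 and 12046407 at 2% CO2. In the shallowest library, 2% CO2 replicate 2, a single count equals 5.60 CPM (counts scaled to a library total of 1e6) and a gene with no counts may lie at up to 16.8 CPM, a limit that covers counting error only. In the deepest library the same limit is 0.243 CPM. Ribosomal RNA took 0.48, 0.59, 0.56, 0.53 and 0.61% of the counts at 10% CO2 and 0.35, 0.54, 0.40, 0.39 and 0.35% at 2% CO2 in replicates 1 to 5. The shares of mitochondrial ribosomal RNA and of the 50 most abundant genes were also lower at 2% CO2 in all 5 pairs of replicates. In a principal component analysis of the tested genes, 2% CO2 replicate 2 lay at 169 on the first component (51.0% of the variance) and the other libraries between -32.3 and 4.9. On the second component (18.5%) 2% CO2 replicate 3 lay at -77.1 and the other libraries between -30.1 and 42.0. Over the 3856 genes of at least 50 CPM, 2% CO2 replicate 2 did not stand apart on the first component, which there parted the batches. The second component (19.4%) there parted the CO2 levels. On the third (11.5%) 2% CO2 replicate 2 lay at -16.6 and the other libraries between -5.88 and 12.5. Nothing states that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

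**Figure D1:**
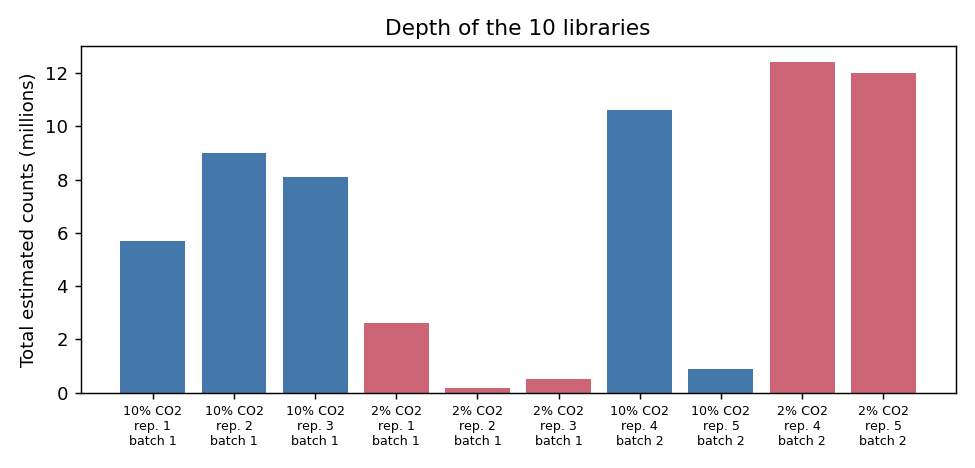
Total estimated counts in units of 1e6 (vertical axis) for each of the 10 libraries (horizontal axis), ordered by batch, with 10% CO2 in blue and 2% CO2 in red. The totals run from 178676 in 2% CO2 replicate 2 to 12354538 in 2% CO2 replicate 4, and the deeper CO2 level differs between the batches.

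The first question was which transcripts differed between 2% and 10% CO2. After 24 h at 2% CO2, 14 of 16 contractile genes, 17 of 35 matrix genes and 14 of 22 genes of the unfolded protein response were lower, while 13 of 18 V-ATPase genes, 13 of 47 lysosomal hydrolase genes and 9 of 30 lysosomal membrane genes were higher. Of these lists, only the contractile one held with an estimated correlation (adjusted p = 0.0151), against 0.294 for the hydrolases and 0.094 for each of the others. Myl9, a myosin regulatory light chain, was at 95.8 ± 26.9 CPM at 2% CO2 and 291 ± 48.0 CPM at 10% CO2 (mean ± SD, n = 5 each), a log2 fold change of -1.68 ± 0.11 (SE). Mt1, a metallothionein that binds zinc and copper, was at 161 ± 15.8 CPM against 54.5 ± 7.13 CPM (SD, n = 5 each), a log2 fold change of 1.57 ± 0.11 (SE). These genes shared the smallest adjusted p, 1.31e-07 by the edgeR quasi-likelihood test.

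Of 13198 genes tested, 1588 (12%) differed between the CO2 levels with batch in the model, 700 higher and 888 lower at 2% CO2. Most differences were modest: the median absolute log2 fold change of the called genes was 0.60, and 85 genes were higher and 167 lower by at least 2-fold. The libraries of both CO2 levels did not overlap at all for 576 of the called genes (36.3%), and for 726 of all tested genes (5.50%), where chance gives 0.794%. With scaling to the library total in place of TMM, 1031 genes were higher and 614 lower, so the balance of directions depended on the scaling. Without 10% CO2 replicate 4 the count was 736, and without 2% CO2 replicate 4 it was 1014.

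The difference was also taken within each batch. Batch 1 alone gave 763 genes (326 higher, 437 lower) and batch 2 alone 267 genes (124 higher, 143 lower). Among 12185 genes tested in both, 58 were called higher in both batches and 91 lower in both, where independent lists would share 3.23 and 4.94, and 0 were called in opposite directions. Of the genes called in batch 1, 666 of 759 (87.7%) had the same sign in batch 2. Without the batch term 351 genes were called. Across genes, which are not independent replicates, the log2 fold changes of the batches had a Pearson r of 0.395, and of 0.560 over the 5443 genes above a log2 CPM of 5.

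Of the 12 genes with the greatest falls at 2% CO2, 4 belonged to the contractile list (Lmod1, Cnn1, Actg2 and Myl9), 1 to the matrix list (Col3a1) and 7 to no list. Lmod1 (leiomodin 1, an actin nucleator of smooth muscle) had a log2 fold change of -2.23 ± 0.28 (SE), with 1.74 ± 1.68 CPM at 2% CO2 and 11.7 ± 3.92 CPM at 10% CO2 (SD, n = 5 each). It was at 0 CPM in 2% CO2 replicates 2 and 3, where 3 counts equal 16.8 and 5.92 CPM. Cnn1 (calponin 1, an actin-binding protein) fell by 1.92 on the log2 scale and Actg2 (enteric smooth muscle actin) by 1.89. Col3a1 (the chain of type III collagen) was at 81.3 ± 33.1 CPM against 288 ± 16.1 CPM (SD, n = 5 each), a log2 fold change of -1.75. Tgm2, a transglutaminase that crosslinks proteins, had a log2 fold change of -2.00 and Crispld2 of -2.06. Rpl22l1, a paralog of ribosomal protein L22, had one of -1.67. All 10 libraries gave it fractional counts, which can arise from reads shared with related sequences, so its value is uncertain. Gpr153, Kctd15, Lrrc17 and Tmem119 completed the 12 lowest genes, with log2 fold changes of -1.99, -1.89, -1.70 and -1.66. All of these but Lrrc17 were at 0 CPM in 2% CO2 replicate 2, the shallowest library.

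Among the genes with the greatest rises at 2% CO2, Grem1 (gremlin 1, a secreted antagonist of bone morphogenetic proteins) stood first with a log2 fold change of 2.51 ± 0.22 (SE), from 2.61 ± 0.611 CPM at 10% CO2 to 13.7 ± 3.29 CPM at 2% CO2 (SD, n = 5 each). Lgals3 (galectin-3, a lectin that gathers on damaged lysosomes) rose by 1.96 and Gpnmb (a transmembrane glycoprotein known as a target of the MiT/TFE transcription factors) by 1.77 on the log2 scale. Mt2, the other abundant metallothionein, rose by 1.70 and Zfas1, a non-coding host transcript of small nucleolar RNAs, by 1.62. Aqp5 (a water channel) and Igfbp3 (a binding protein of insulin-like growth factors) rose by 1.99 and 1.97, and Dcxr and Dlk2 by 1.51 and 1.42. Aqp5 was at 0 CPM in 2% CO2 replicate 2, the shallowest library. Fabp3 (1.55) and Anxa8 (1.44) passed with adjusted p of 0.0455 and 0.0358 by edgeR. Their calls were each lost without 10% CO2 replicates 3 or 4 or 2% CO2 replicates 1, 3 or 4, that of Fabp3 also without 10% CO2 replicate 5 and that of Anxa8 without 2% CO2 replicate 5, at adjusted p of up to 0.230 and 0.218.

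The contractile cytoskeleton list moved most. Of its 16 tested members 0 rose, 14 fell and 2 did not pass, and all 16 fell when adjusted over the list alone. Its median log2 fold change was -0.70, with -0.76 in batch 1 and -0.67 in batch 2. Acta2 (smooth muscle actin, ENSMUSG00000035783) was at 2155 ± 321 CPM at 2% CO2 and 5708 ± 632 CPM at 10% CO2 (SD, n = 5 each), and Tpm2 (tropomyosin 2) had a log2 fold change of -0.91. By limma camera the adjusted p was 4.11e-15 with the preset correlation, and it was 0.0151 with an estimated correlation. It was the only list of the 34 tested to hold with an estimated correlation, and 13 were called with the preset one.

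Genes of the unfolded protein response expand the folding capacity of the endoplasmic reticulum. Of 22 tested members 0 rose, 14 fell and 8 did not pass, and 1 rose and 15 fell when adjusted over the list alone. Hspa5 (BiP, the main chaperone of this compartment, ENSMUSG00000026864) was at 357 ± 36.8 CPM against 831 ± 40.0 CPM (SD, n = 5 each), a log2 fold change of -1.20. Xbp1, a transcription factor of this response, fell by 1.54, Hsp90b1 by 0.99 and Calr by 0.85. The median was -0.48 (-0.56 in batch 1, -0.35 in batch 2), with a camera adjusted p of 2.02e-10 that became 0.094 with an estimated correlation.

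Of 35 tested extracellular matrix genes 17 fell, 17 did not pass and 1 rose, and 22 fell and 1 rose when adjusted over the list alone. Col1a1 (the alpha 1 chain of type I collagen) was at 2015 ± 833 CPM at 2% CO2 and 4307 ± 1252 CPM at 10% CO2 (SD, n = 5 each), a log2 fold change of -1.15. Col1a2 fell by 0.95 and Serpinh1, the collagen chaperone HSP47, by 0.87. The member that rose was Timp2, an inhibitor of matrix metalloproteinases, named after its value was seen (log2 fold change 0.37). The median was -0.48, -0.48 in batch 1 and -0.41 in batch 2, and the camera adjusted p was 7.60e-09, or 0.094 with an estimated correlation.

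Of 20 heat shock genes, mostly cytosolic chaperones, 8 fell, 12 did not pass and 0 rose, or 9 fell when adjusted over the list alone. Hspb1 was at 80.7 ± 20.9 CPM at 2% CO2 and 172 ± 23.6 CPM at 10% CO2 (SD, n = 5 each), and the log2 fold change of Hspb8 was -0.98, that of Hspa8 (with fractional counts in all 10 libraries) -0.58 and that of Hsph1 -0.52. The camera adjusted p was 0.000106, or 0.163 with an estimated correlation, and the list median was -0.23.

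Autophagy delivers its cargo to the lysosome, and lysosomal genes were examined in several lists. For the V-ATPase, the pump that acidifies lysosomes, 13 of 18 subunit genes rose, 0 fell and 5 did not pass, and 14 rose when adjusted over the list alone. Atp6v0d1 was at 89.5 ± 13.1 CPM at 2% CO2 and 52.7 ± 3.77 CPM at 10% CO2 (SD, n = 5 each), a log2 fold change of 0.72. Atp6v1d rose by 0.81, Atp6ap2 by 0.74 and Atp6ap1 by 0.57. The list median was 0.40 (0.43 in batch 1, 0.41 in batch 2), with a camera adjusted p of 4.67e-09, or 0.094 with an estimated correlation. Atp6v1h rose by 0.38 (edgeR adjusted p = 0.0239), a call lost without 10% CO2 replicates 3 or 4 or 2% CO2 replicates 3 or 4 at adjusted p of up to 0.120.

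Among lysosomal hydrolases, 13 of 47 tested genes rose, 0 fell and 34 did not pass, or 17 rose when adjusted over the list alone. Ctsd (cathepsin D, an aspartic protease) was at 387 ± 59.2 CPM against 233 ± 26.7 CPM (SD, n = 5 each), a log2 fold change of 0.76. Ctsa rose by 0.89 and Neu1 (a sialidase) by 0.83. The cysteine cathepsins Ctsb and Ctsl did not pass, with log2 fold changes of 0.29 ± 0.11 and 0.22 ± 0.11 (SE) and edgeR adjusted p of 0.0810 and 0.197. Ctsb did pass with DESeq2 (adjusted p = 0.0358), limma-voom (0.0491), scaling to the library total (0.0260) and GC and length trends removed (0.0396). The list median was 0.25, and the camera adjusted p was 2.89e-05, or 0.294 with an estimated correlation. By fry the adjusted p was 0.119.

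Lysosomal membrane protein genes gave 9 rises and 1 fall among 30 members, with 20 that did not pass, or 10 rises and 2 falls when adjusted over the list alone. Lamp1, a major glycoprotein of the lysosomal membrane (ENSMUSG00000031447), was at 584 ± 139 CPM at 2% CO2 and 334 ± 80.1 CPM at 10% CO2 (SD, n = 5 each), a log2 fold change of 0.81 with 0.80 in batch 1 and 0.85 in batch 2. Ctns (the cystine transporter) rose by 1.16, Clcn7 (a chloride-proton exchanger) by 0.74 and Lamp2 by 0.48. Mcoln1, a lysosomal calcium channel, rose by 0.60, a call lost without 10% CO2 replicate 4 (edgeR adjusted p = 0.0531). The member that fell was Tpcn1, an endolysosomal cation channel, at -0.98, named after its value was seen. Npc1, which exports cholesterol from lysosomes, had a log2 fold change of 0.24 ± 0.15 (SE) and did not pass (edgeR adjusted p = 0.329). The list median was 0.20, with a camera adjusted p of 0.000452, or 0.094 with an estimated correlation.

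Regulators of mTORC1 and of TFEB, the kinase complex and the transcription factor that tie lysosomal gene expression to nutrients, gave 7 rises, 0 falls and 21 members that did not pass among 28, or 8 rises when adjusted over the list alone. Flcn (folliculin) rose by 1.00, Rragc by 0.59 and Lamtor3 by 0.50, the last of which was lost without 10% CO2 replicate 4 (edgeR adjusted p = 0.0532). Fnip1, a partner of folliculin, rose by 0.51 and was lost without the same library (adjusted p = 0.0870). The transcription factor genes themselves did not pass: Tfeb had a log2 fold change of -0.07 ± 0.28 and Tfe3 one of -0.15 ± 0.12 (SE), with edgeR adjusted p of 0.929 and 0.463. Tfeb was low, at 2.85 ± 1.71 CPM at 2% CO2 and 3.74 ± 1.18 CPM at 10% CO2 (SD, n = 5 each). It was at 0 CPM in 2% CO2 replicate 2, the shallowest library, so a change of it could go unseen. Rragd had 79 counts over all libraries and was too low to test. The camera adjusted p of the list was 0.00676 and its median 0.21, with an adjusted p of 0.176 under an estimated correlation and 0.0509 in batch 1 alone.

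**Figure D2:**
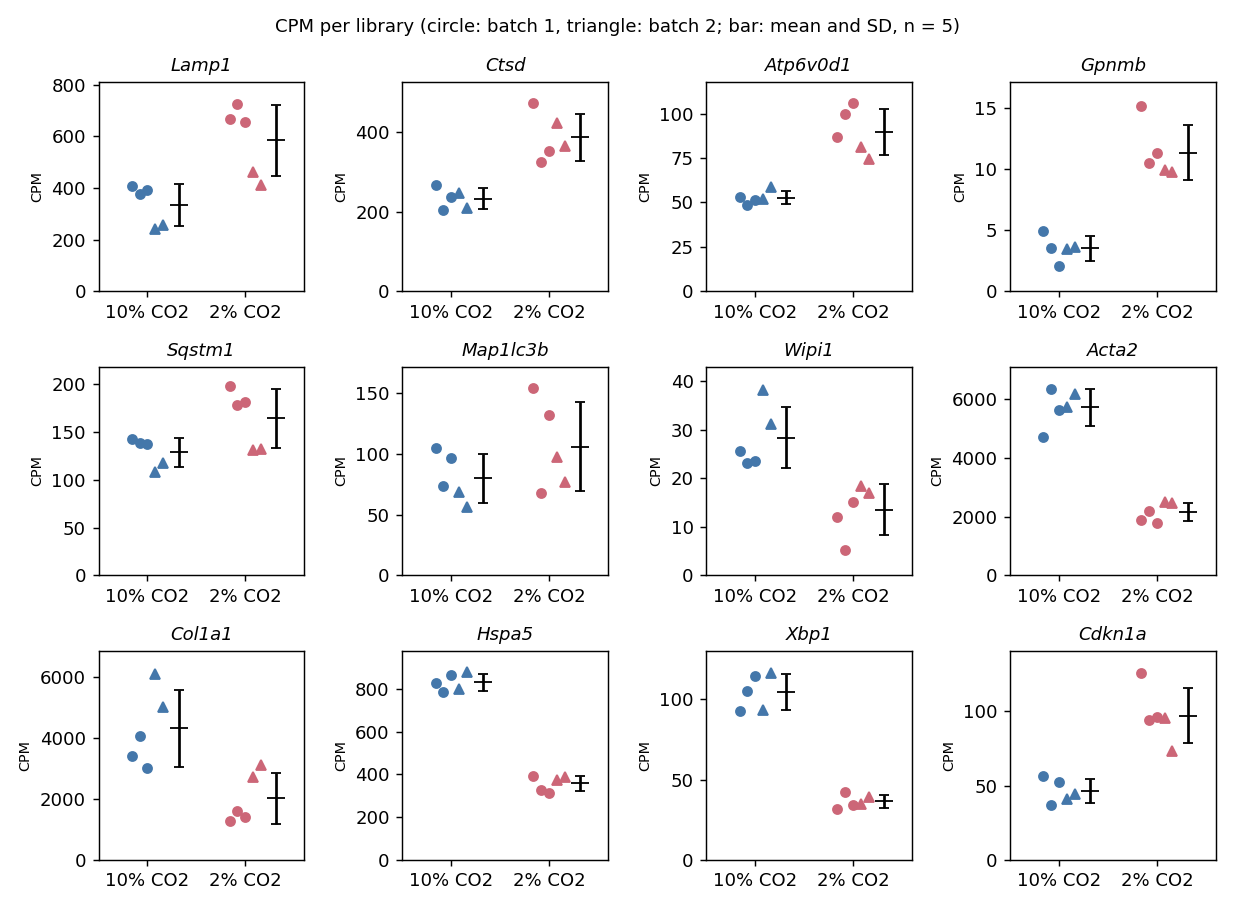
CPM per library (vertical axes, from 0) for 12 genes at 10% and 2% CO2, with circles for batch 1, triangles for batch 2, and the mean with SD (n = 5) beside each group. Lamp1 averages 334 CPM at 10% CO2 and 584 CPM at 2% CO2, and Acta2 5708 and 2155 CPM.

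Genes of the autophagy machinery itself were not called as a list. In the core machinery 6 of 35 tested members rose, 2 fell and 27 did not pass, or 7 and 3 when adjusted over the list alone, and the camera adjusted p was 0.174 (median 0.12), or 0.0259 with no filter on low counts. Map1lc3b (LC3B, which coats the autophagosome membrane) was at 106 ± 36.7 CPM at 2% CO2 and 80.1 ± 20.2 CPM at 10% CO2 (SD, n = 5 each), a log2 fold change of 0.49 ± 0.14 (SE, edgeR adjusted p = 0.0326). All 10 libraries gave it fractional counts, and the call was lost without 10% CO2 replicates 2, 3, 4 or 5 or 2% CO2 replicates 1, 3 or 4, at adjusted p between 0.0571 and 0.144. Wipi1, which binds phosphatidylinositol 3-phosphate at forming autophagosomes, fell by 1.02 (13.6 ± 5.22 against 28.4 ± 6.35 CPM, SD, n = 5 each), and the protease gene Atg4d fell by 0.72. Uvrag and Wdr45 rose by 0.55 and 0.74, and both calls were lost without 10% CO2 replicate 4 (edgeR adjusted p = 0.133 and 0.104), that of Uvrag also without 2% CO2 replicate 1 (0.0640) and that of Wdr45 without 2% CO2 replicate 4 (0.0624). Ulk1, the kinase that starts autophagy, and Gabarapl1 did not pass, at log2 fold changes of -0.31 ± 0.18 and -0.16 ± 0.16 (SE).

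Of 20 autophagy receptor genes 4 rose, 0 fell and 16 did not pass, or 7 rose and 1 fell when adjusted over the list alone. Retreg1 (a receptor for the endoplasmic reticulum) rose by 1.11 and Bnip3 (a mitochondrial receptor) by 0.97. Sqstm1 (p62, a receptor that is itself degraded by autophagy) was at 164 ± 30.5 CPM at 2% CO2 and 129 ± 15.1 CPM at 10% CO2 (SD, n = 5 each), a log2 fold change of 0.35 ± 0.09 (SE, edgeR adjusted p = 0.0192), and the call was lost without 10% CO2 replicates 3 or 4 or 2% CO2 replicate 1, at adjusted p of 0.0561, 0.0704 and 0.0634. Tex264 rose by 0.41, a call lost in 8 of the 10 fits that left out a library, all but those without 10% CO2 replicate 5 and 2% CO2 replicate 2. The camera adjusted p of the list was 0.0560 and its median 0.10, and the list passed without 10% CO2 replicate 3 (0.0419) or 2% CO2 replicate 2 (0.0344), by fry (0.0237), with scaling to the library total (0.0349), with no filter on low counts (0.00341), with voom weights (0.0341) and with GC and length trends removed (0.0428).

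Genes for the fusion of autophagosomes with lysosomes gave 3 rises, 1 fall and 18 members that did not pass among 22, or 5 and 1 when adjusted over the list alone (camera adjusted p = 0.239, median 0.12). Rab7, a small GTPase of late endosomes, rose by 0.36. Vps33a rose by 0.62, lost without 10% CO2 replicate 4 (edgeR adjusted p = 0.159), and the SNARE gene Ykt6 fell by 0.40, lost without 2% CO2 replicate 1 (0.0533). Arl8b rose by 0.38, a call lost without 10% CO2 replicates 1 or 4 or 2% CO2 replicates 3, 4 or 5, at adjusted p of up to 0.159. The syntaxin partner Vamp7 was not matched by name and was not analysed here.

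A change of CO2 changes bicarbonate and pH in the medium, and genes that handle them were asked about separately. In the pH and bicarbonate list 0 of 18 tested members rose, 1 fell and 17 did not pass, the same when adjusted over the list alone, with a camera adjusted p of 0.967. The gene that fell was Nherf1, a scaffold protein under the cell membrane, at -0.60. The bicarbonate transporters Slc4a7 and Slc4a4 had log2 fold changes of 0.03 ± 0.13 and 0.27 ± 0.17 and the lactate transporter Slc16a3 -0.01 ± 0.14 (SE), with edgeR adjusted p between 0.364 and 0.987. Carbonic anhydrase 12 (Car12) had a log2 fold change of -1.09 ± 0.38 (SE) at a mean of 1.67 CPM over all libraries, which did not pass (adjusted p = 0.0718) but did without 10% CO2 replicate 5 (0.0169). Car9 had 23 counts over all libraries and was too low to test. In the list of bicarbonate-fixing enzymes 1 of 10 tested members fell, 9 did not pass and 0 rose, also when adjusted over the list alone. The member that fell was Pck2 (mitochondrial phosphoenolpyruvate carboxykinase) at -0.99, an enzyme that releases CO2 and does not fix bicarbonate. The list had a camera adjusted p of 0.843 (0.0208 by fry).

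**Figure D3:**
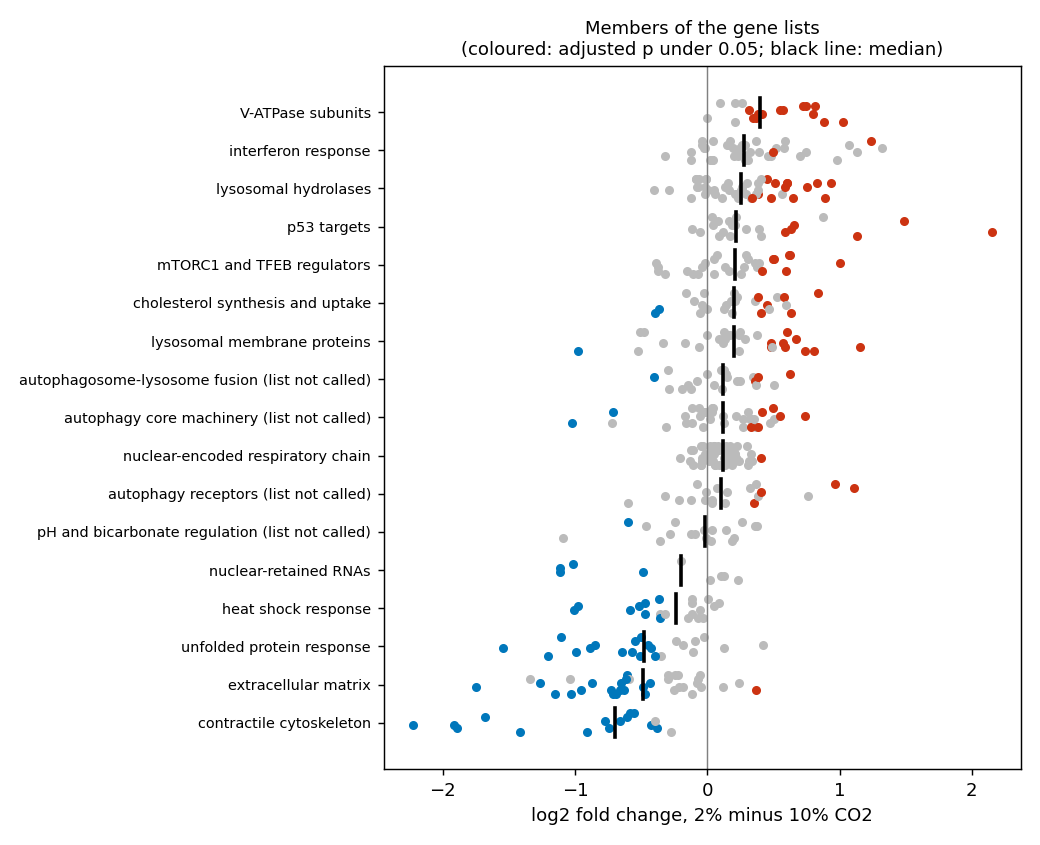
Log2 fold change at 2% minus 10% CO2 (horizontal axis) of every tested member of the 13 called lists and of 4 lists that were not called (vertical axis), with members at an adjusted p under 0.05 in red (higher) or blue (lower), the others in grey, and black lines for the medians. The contractile list lies lowest, at a median of -0.70, and the V-ATPase list highest, at 0.40.

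Lists of stress and of sterol metabolism were examined next. For targets of p53, 6 of 22 members rose, 0 fell and 16 did not pass, or 9 rose when adjusted over the list alone. Cdkn1a (the cell cycle inhibitor p21) rose by 1.13, Perp by 2.15, Ccng1 by 0.64 and Mdm2 by 0.59. Perp was low, at 5.59 ± 3.59 CPM against 1.58 ± 0.556 CPM (SD, n = 5 each). It was at 0 CPM in 2% CO2 replicate 2 and was not tested in batch 1 alone. T antigen inactivates p53, and whether p53 acted on these genes was not tested. The camera adjusted p of the p53 list was 0.00676, or 0.390 with an estimated correlation and 0.0525 without 2% CO2 replicate 1. In batch 1 alone it was 0.0538. In cholesterol synthesis and uptake 6 of 25 members rose, among them Cyp51 (0.58), Msmo1 (0.63) and Tm7sf2 (0.84), and 2 fell, among them, named after its value was seen, Hmgcs1 (-0.40), while 17 did not pass. Adjusted over the list alone, 8 rose and 2 fell. The call of Tm7sf2 was lost without 2% CO2 replicate 1 (edgeR adjusted p = 0.0590). The cholesterol list had a camera adjusted p of 0.0393, or 0.566 with an estimated correlation, and was lost without 10% CO2 replicates 2 or 5 or 2% CO2 replicates 1 or 4, at adjusted p between 0.0706 and 0.153. It was also lost with a filter of 10 CPM in 5 libraries (0.0993) and in batch 1 alone (0.281), and its median of 0.20 became 0.11 without 2% CO2 replicate 4.

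The interferon response list gave 2 rises (Mx2 and Xaf1, antiviral and apoptotic effectors), 0 falls and 38 members that did not pass among 40, or 1 rise when adjusted over the list alone. Its camera adjusted p was 0.00252, or 0.644 with an estimated correlation, 0.136 without 2% CO2 replicate 5 and 0.397 in batch 2 alone. Its median of 0.27 became 0.10 without 10% CO2 replicate 4 (0.0485) and 0.03 without 2% CO2 replicate 5. The call of Mx2 was lost without 10% CO2 replicate 4 (edgeR adjusted p = 0.0711) and that of Xaf1 in 7 of the 10 fits that left out a library, at up to 0.147. In the nuclear-encoded respiratory chain 1 of 60 members rose, 0 fell and 59 did not pass, also when adjusted over the list alone. The camera adjusted p of the respiratory chain list was 0.0143 at a median of 0.12, or 0.696 with an estimated correlation. With GC and length trends removed the median was 0.05 and the call was lost (adjusted p = 0.25). The direction of this list differed between the batches, with a median of 0.29 in batch 1 and -0.10 in batch 2, and the call was lost without 10% CO2 replicate 2 (0.279) or 2% CO2 replicate 1 (0.452). The respiratory chain median was 0.05 and -0.01 in those fits, and 0.18 without 10% CO2 replicate 5.

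In the list of nuclear-retained RNAs 4 of 9 tested members fell, 0 rose and 5 did not pass, the same when adjusted over the list alone. The members that fell were the imprinted transcripts Meg3 (-1.11), Rian (-1.12) and Mirg (-1.01), which lie in a shared cluster, and Norad (-0.48). Norad is known as a mainly cytoplasmic RNA, so the falls of nuclear-retained RNAs came from that cluster alone. Mirg was lost without 10% CO2 replicate 4 (edgeR adjusted p = 0.0773) and Norad without 2% CO2 replicate 1 (0.0870). The list had a camera adjusted p of 0.0393, or 0.566 with an estimated correlation and 0.0528 with the replicate number as a block. Its median was -0.20, with -0.54 in batch 1 and 0.09 in batch 2. With GC and length trends removed the median was 0.02 (adjusted p = 0.0710), and the call was also lost with a filter of 10 CPM in 5 libraries (0.0848) and without the 3 shallowest libraries (0.105). It was lost without 10% CO2 replicates 1 or 2 or 2% CO2 replicates 1, 2 or 3, at adjusted p between 0.0525 and 0.114. The median was -0.13 without 10% CO2 replicate 2, -0.09 without 2% CO2 replicate 3 and -0.38 without 10% CO2 replicate 5.

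The ATF4 stress response list had members in both directions, with 5 rises, 5 falls and 28 that did not pass among 38, or 6 and 7 when adjusted over the list alone (camera adjusted p = 0.484). Ddit3 (CHOP, a transcription factor of stressed cells) rose by 1.28, Atf3 by 1.28 and Nupr1 by 0.94, while the metabolic gene Pck2 fell by 0.99. The other members called, named after their values were seen, were Atf4 and Ppp1r15a, higher, and Aldh1l2, Slc7a5, Mthfd2 and Gars1, lower. The list median was 0.11 in batch 1 and -0.27 in batch 2, and the list was called in both batches taken alone, in opposite directions (camera adjusted p = 0.0329 and 0.0285).

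Cell cycle lists were not called with the preset correlation. In DNA replication 1 of 31 members rose, Prim1, 0 fell and 30 did not pass (camera adjusted p = 0.313, median 0.08), and in mitosis 2 of 30 fell, Ccnb2 (-0.57) and Plk1 (-0.42), 0 rose and 28 did not pass (0.0671, median -0.14), both also when adjusted over the list alone. Prim1 was lost without 10% CO2 replicates 3 or 4 or 2% CO2 replicates 1 or 4 and Plk1 without 10% CO2 replicates 3 or 4 or 2% CO2 replicates 1 or 4, and the mitosis list passed without 10% CO2 replicates 1, 3 or 4, at adjusted p between 0.0331 and 0.0485, with voom weights (0.0356) and with GC and length trends removed (0.0249). Replication-dependent histones gave 1 rise (H1f2), 1 fall (H1f5) and 16 that did not pass (0.214), also when adjusted over the list alone, and H1f2 was lost without 2% CO2 replicate 1, where its log2 fold change of 0.53 became 0.32 (edgeR adjusted p = 0.203). The histone list passed, lower, in batch 2 alone (0.00161). Among 76 cytosolic ribosomal protein genes 3 fell, Rpl3 (-0.67), Rpl10a (-0.75) and Rpl27 (-0.41), 0 rose and 73 did not pass, also when adjusted over the list alone, with a median of 0.09 in batch 1 and -0.33 in batch 2. These genes have many processed pseudogenes and fractional counts in 9 or 10 libraries, and Rpl27 was lost without 2% CO2 replicate 4. That list had a camera adjusted p of 0.0695 and passed without 10% CO2 replicates 2, 3 or 4 or 2% CO2 replicate 1, at adjusted p from 0.000239 to 0.0485. It also passed, lower, in batch 2 alone (4.34e-11), with GC and length trends removed (median -0.16, 9.25e-05) and with voom weights (0.00598), and passed as higher in batch 1 alone (0.0291). Mitochondrially encoded genes gave 1 fall among 13, mt-Nd6 (-0.97), with 12 that did not pass (camera adjusted p = 0.239), also when adjusted over the list alone. The mitochondrial list passed with voom weights (0.0356) and without the 3 shallowest libraries (0.00288). mt-Nd6 is encoded on the strand opposite to most mitochondrial genes, and whether the counting used strand is not given in the sources used here.

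In the remaining signalling and metabolic lists few members passed. YAP targets gave 3 falls (Ccn1, Ccn2 and Ankrd1), 0 rises and 16 that did not pass, or 4 falls and 1 rise when adjusted over the list alone. The YAP list had a camera adjusted p of 0.0695 and passed without 10% CO2 replicates 3, 4 or 5 or 2% CO2 replicates 4 or 5, at adjusted p from 0.0166 to 0.0485. Ankrd1 was lost in 7 of the fits that left out a library, at up to 0.175, Ccn2 in 8, at up to 0.161, and Ccn1 in 0. The circadian clock list gave 3 rises (Nr1d2, Ciart and Dbp), 1 fall (Nfil3) and 13 that did not pass, or 4 and 1 when adjusted over the list alone, at 0.0605, and passed without 10% CO2 replicate 2 or 2% CO2 replicate 2 (0.0290 and 0.0289). Each of these 4 genes was lost in 1 or 2 of the fits that left out a library, at adjusted p of up to 0.184. Genes of the hypoxia response gave 5 rises (Bnip3, Kdm3a, Fam162a, Higd1a and, named after its value was seen, Ankrd37), 0 falls and 16 that did not pass, or 8 rises when adjusted over the list alone, at 0.0906, and passed without 2% CO2 replicate 2 (0.0289). Kdm3a was lost without 10% CO2 replicate 4 or 2% CO2 replicate 1, Fam162a without these or 10% CO2 replicate 3, and Higd1a in 8 of these fits, at adjusted p of up to 0.104, 0.0620 and 0.133. No member of the glycolysis list passed of 19 (0.0671), with 0 also when adjusted over the list alone, and the list passed without 10% CO2 replicate 3 (0.0419). With voom weights the YAP (0.0376), circadian (0.0376), hypoxia (0.0348) and glycolysis (0.0356) lists passed. Without the 3 shallowest libraries YAP (0.0262) and hypoxia (0.0194) did, with GC and length trends removed circadian (0.0428) and glycolysis (0.0226), and with no filter on low counts circadian (0.0135), hypoxia (0.0135) and glycolysis (0.00533). The YAP list also passed in batch 1 alone (0.00315), the circadian list in batch 2 alone (0.00934) and the glycolysis list with scaling to the library total (0.0349).

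Immediate early genes gave 3 rises (Atf3, Klf2 and Fosl1), 2 falls (Zfp36 and, named after its value was seen, Egr1) and 16 that did not pass, the same when adjusted over the list alone (camera adjusted p = 0.308), and Fosl1 was lost without 10% CO2 replicate 4 (edgeR adjusted p = 0.0744). Of 22 inflammatory genes of the NF-kB list 1 rose (Cxcl10), 1 fell (Vcam1) and 20 did not pass, or 0 and 1 when adjusted over the list alone (0.861). Cxcl10 was lost in 7 of the fits that left out a library, at up to 0.102, and Vcam1 without 10% CO2 replicate 4 or 2% CO2 replicate 4. NRF2 targets gave 1 fall (Abcc1) and 21 that did not pass (0.444), and fatty acid synthesis 1 fall (Scd2) and 14 that did not pass (0.444), with 0 for both when adjusted over the list alone, and both genes were lost in 7 or more of the fits that left out a library. Without 2% CO2 replicate 1 the log2 fold change of Abcc1 went from -0.42 to -0.25 (edgeR adjusted p = 0.211). For the pH, ATF4 and NF-kB lists the camera direction was up while the median lay below 0, and for the last of these the mean lay above 0.

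Markers of cell types were examined next. Of the fibroblast list 8 members were tested, 2 fell (Thy1 at -0.74 and Vim at -0.42), 0 rose and 6 did not pass, or 1 rose and 4 fell when adjusted over the list alone. The fibroblast list had a median of -0.34 and a camera adjusted p of 0.114, and it passed by fry (0.0153) and with no filter on low counts (0.0439). Of 5 tested neural markers 1 fell, Nes (71.2 ± 13.5 against 87.5 ± 12.8 CPM, SD, n = 5 each), and 4 did not pass, or 2 fell when adjusted over the list alone (0.239, or 0.0402 with voom weights and 0.0309 in batch 2 alone), and Nes was lost in 5 of the fits that left out a library, at up to 0.281. Too few members of the other marker lists were expressed for a list test: 1 of 11 macrophage, 2 of 9 endothelial, 2 of 10 epithelial, 2 of 12 skeletal muscle and 3 of 10 adipocyte markers were tested. Adjusted over the list alone, 1 macrophage marker (Cd14) and 1 endothelial marker rose, 1 skeletal muscle marker (Acta1) fell and 0 epithelial or adipocyte markers passed. Over all genes Cd14 (0.94) and Acta1 (-0.96), named after their values were seen, did not pass, with edgeR adjusted p of 0.0517 and 0.0991. Of these, Kdr, an endothelial receptor, rose by 0.98 at 9.25 ± 3.35 against 5.40 ± 1.38 CPM (SD, n = 5 each), a call lost without 10% CO2 replicate 4 (edgeR adjusted p = 0.155) or 2% CO2 replicate 4 (0.0675).

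The next question was whether the CO2 difference itself differed between the batches. No gene passed for the CO2 by batch interaction with edgeR (smallest adjusted p = 0.324), where 1155 of 13198 genes (8.75%) had an unadjusted p under 0.05. DESeq2 called 48 genes, among them the asparagine synthetase gene Asns and the respiratory chain gene Ndufa11, named after their values were seen, and most of the others were pseudogenes or predicted genes. The edgeR count was 135 without 10% CO2 replicate 4, 4 without 2% CO2 replicate 1, 1 without 10% CO2 replicate 5 and 1 without 2% CO2 replicate 4, and with no filter on low counts it was 104. On simulated counts of this design the test found 20% of interactions of 2-fold and 64.6% of those of 3-fold, so smaller ones would go undetected.

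Batch made a wider difference than CO2. Between batch 2 and batch 1, with CO2 in the model, 4749 genes differed, 2301 higher and 2448 lower in batch 2, of which 921 by at least 2-fold. By camera, genes of the nuclear-encoded respiratory chain (27 of 60 lower, 2 higher, median -0.32, adjusted p = 0.000493), cytosolic ribosomal proteins (27 of 76 lower, 8 higher, adjusted p = 0.0314) and the interferon response (7 of 40 lower, 0 higher, adjusted p = 0.0412) were called lower in batch 2. With an estimated correlation, tried after the data were seen, the adjusted p was 0.949 for each of these lists. What the batches were is not stated, and each held both CO2 levels.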

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

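A library was set apart where its gap to the nearest of the other libraries of its CO2 level exceeded 0.71 of the range of the 5. Over 262 groups of 5 tested (130 genes and the library totals, at both CO2 levels) this happened in 10. For independent values of 1 normal distribution about 13.1, or 1 in 20, would be set apart. Here most of the genes had been named because they were called, and each group spans both batches. The number expected is therefore only a rough guide, against which the flags were not more frequent. No explanation was tested for any of them.

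At 10% CO2, replicate 5 had 55.2 CPM of Mt2 against 23.5 to 30.8 in the other libraries and 106 CPM of Ykt6 against 85.7 to 90.9. Replicate 1 had 826 CPM of Calr against 708 to 738 and 85.5 CPM of Prim1 against 66.5 to 69.0. At 2% CO2, replicate 5 had 9.94 CPM of Tgm2 against 3.48 to 5.25 and 139 CPM of Col3a1 against 57.8 to 76.8, both still below the 10% CO2 mean. Replicate 1 had 15.2 CPM of Gpnmb against 9.78 to 11.4 and 144 CPM of Nupr1 against 101 to 110. Replicate 2, the shallowest library, where 1 count is 5.60 CPM, had 15.8 CPM of Retreg1 against 44.9 to 54.9. Replicate 4 had 2160 CPM of Ccn2 against 1230 to 1460.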

How the results depend on the processing

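The number of CO2 genes (1588) stayed within 1.5 times under RLE (1624), library total scaling (1645), DESeq2 (1631), limma-voom (1550), both filters, the replicate block (1927) and, chosen after seeing the data, without the 3 shallowest libraries (1237) or with GC and length trends removed (2028). It was 351 without the batch term, 763 in batch 1 alone, 267 in batch 2 alone, 543 against a fold of 1.2 and 160 with every library thinned to the smallest total. Each batch alone has fewer libraries and the thinned fit fewer counts. Only 3516 genes were tested in the thinned fit, among them 570 of the 1588, of which 142 stayed called. A first thinning, which removes counts by a multinomial draw, gave 0 genes (44 at an unadjusted p under 0.05) and was set aside: it added noise to the deep libraries, whose lowest correlation of log counts with the full library was 0.724, against 0.889 for the binomial draw used. Leaving out a library gave 736 to 1724 CO2 genes, 0 to 135 interaction genes, 3253 to 5260 batch genes and 10 to 18 lists. The interaction count of 0 became 104 with no filter and 48 with DESeq2, and the cause was not tested. The number of lists called, 13, was 1 with an estimated correlation, 9 by fry and 22 with voom weights. By fry the calls of the hydrolase (adjusted p = 0.119), mTORC1 and TFEB (0.112), p53 (0.172) and nuclear-retained (0.226) lists were lost. So were those of the cholesterol (0.377), interferon (0.484) and respiratory chain (0.611) lists. The contractile (1.26e-05), unfolded protein (0.000305), matrix (0.000867), V-ATPase (0.00314), heat shock (0.00314) and lysosomal membrane (0.00779) lists held by fry. The autophagy receptor (0.0237), fibroblast (0.0153) and bicarbonate-fixing (0.0208) lists passed by fry though not called in the main test. The ATF4 list had a median of -0.27 and the respiratory chain list one of -0.10 in batch 2 alone, and the ribosomal protein list one of 0.089 in batch 1 alone, each called against the direction over all libraries, and the cause was not tested. Among lists, 309 of 340 leave-one-out results and 374 of 441 others kept their direction and side of the threshold. For named genes this held for 1150 of 1295 and 1095 of 1298, and 0 reversed. The replicate block lost the call of the nuclear-retained list (adjusted p = 0.0528) and changed no other call among the lists and named genes. Depth limits genes of low level most, since 3 counts equal 16.8 CPM in the shallowest library.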

Other observations

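The tests of the 6 gene groups of this part, the test on dividing cells and the fit with GC and length trends removed were chosen only after the data were seen. Because the groups were picked with the values of their members in view, their p-values decide nothing about a cause. They are also unadjusted, whereas those of the fixed lists are adjusted over the 34 lists, so they cannot be set side by side. With an estimated correlation, the unadjusted camera p was 0.00643 for the V-ATPase list, 0.011 for the unfolded protein list and 0.0868 for the hydrolases.

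Of 36 genes of transport from the endoplasmic reticulum to the Golgi, 13 fell at 2% CO2, 0 rose and 23 did not pass, and the median log2 fold change was -0.31 (-0.39 in batch 1, -0.22 in batch 2). Sec24d, a cargo adaptor of COPII vesicles, fell by 1.55, Sec23a by 1.01 and the retrieval receptor gene Kdelr3 by 0.96. Camera gave p = 1.41e-09, or 0.00451 with an estimated correlation, and whether these genes moved together with the unfolded protein list was not tested. Actin and SRF-linked genes outside the contractile list gave 17 falls and 0 rises among 20, with a median of -0.66. Tmsb4x (thymosin beta 4, which binds actin monomers) fell by 1.16, Fblim1 by 0.98 and Actb by 0.84 (camera p = 7.05e-15, or 0.00107 with an estimated correlation). For TGF-beta ligands and targets 8 fell and 2 rose among 21. Tgfb2 fell by 1.54, Tgfb3 by 1.26 and Fstl3 by 0.95, while the receptor genes Tgfbr2 and Tgfbr3 rose by 0.54 and 0.84 (camera p = 0.000102, or 0.00381 with an estimated correlation).

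Among MiT/TFE-linked genes outside the lysosomal lists, 10 of 16 rose and 1 fell (Wipi1), with a median of 0.50 (0.34 in batch 1, 0.55 in batch 2). Camera gave p = 1.69e-05, or 0.0350 with an estimated correlation. All of these genes but Gpnmb and Hif1a also belong to the autophagy, fusion or mTORC1 and TFEB lists above, so the group largely counts them again. Gpnmb and Flcn, both known targets of these factors, rose, while the transcripts Tfeb and Mitf of the factors did not pass. Tfeb and Mitf were low, Mitf at 2.20 ± 1.81 CPM at 2% CO2 and 1.56 ± 0.496 CPM at 10% CO2 (SD, n = 5 each). Mitf was not tested in batch 1 alone. Activity of the factors was not measured. Iron and metal handling gave 3 rises among 14, Mt1, Mt2 and the transferrin receptor gene Tfrc (1.14), while the ferritin genes Fth1 and Ftl1 did not pass at -0.12 and 0.01. The median of this group was 0.10, and camera gave p = 0.000105, or 0.00778 with an estimated correlation. Non-coding host transcripts of small nucleolar RNAs gave 7 rises, Zfas1 (1.62) and Snhg6 (0.79) among them, and 1 fall (Snhg18) among 16. Their camera p was 0.00518 but 0.396 with an estimated correlation.

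The rise of the V-ATPase and lysosomal lists (median log2 fold change 0.26 over 95 members) was weighed against depth and sequence composition. In batch 2 both 2% CO2 libraries are deep and 1 of the 10% CO2 libraries is shallow. There the median was 0.28 ± 0.04 (SE), above 0, and in batch 1, where the depths are turned, it was 0.30. The same direction under turned depths argues against depth as the cause. Each SE here and in the next paragraph is the SD of the member genes over the root of their number. Member genes are not independent, so this SE does not measure the spread between libraries, of which batch 2 holds 2 per CO2 level. With per-library trends on GC content and transcript length removed the median was 0.25 ± 0.04 (SE), which argues against those trends as the whole cause. A response to CO2 or to the pH of the medium stays open as a hypothesis, since neither was tested apart from the other.

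The fall of the contractile, matrix and unfolded protein lists (median -0.55 over 73 members) was weighed in the same way. It was -0.41 ± 0.07 (SE) in batch 2 alone, against depth as the cause, and -0.49 ± 0.06 (SE) with GC and length trends removed, against those trends as the whole cause. Fewer dividing cells at 2% CO2 as the whole cause would need replication and mitosis genes to fall at least as much. Their lists together had a median of -0.038 ± 0.025 (SE, 61 members, SD 0.196), with -0.064 in batch 1 and 0.029 in batch 2. Taken apart, the DNA replication list had a median of 0.08 and the mitosis list one of -0.14. Both lie above -0.55, which argues against fewer dividing cells as the whole cause only if these lists follow the share of dividing cells. T antigen inactivates the retinoblastoma protein, and whether the lists follow that share in such cells was not tested. Cell density was not measured and stays open, as does a response to CO2.

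The counts were set against other splits of the 10 libraries. Of 100 splits into 5 and 5, drawn with a fixed seed and fitted with batch, 1 (the real one) gave as many CO2 genes. It gave 1588 against 609 for the highest other, so the real split stood apart from the others drawn. The splits were not held within batch, and every other split mixed the CO2 levels in its groups, which can lower its count. Since nothing states that the replicates came from separate cultures, the splits do not exclude a chance difference between cultures. Among the 12 drawn splits that part every same-numbered pair, the real one included, the highest other gave 0. With 12 splits the share cannot fall below 1 in 12, which is above the bound of 0.05 set beforehand, so these splits alone decide nothing. For the number of lists chance is not excluded. Of the 100 splits 12, the real one included, called as many as the 13 of the real split. The highest other called 18 and kept 4 of the 5 libraries of a CO2 level together. Such a split carries part of the CO2 difference, so its count is not one of chance alone. A split with 3 of them together called 16, so the number of lists decides nothing either way. Of 100 splits into 6 and 4, only the real batches gave as many as 4749 batch genes, and the highest other gave 799. The interaction compares groups of 2 and 3 libraries, so no splits were counted.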
